A study of Mus musculus with 54 samples.

How the data were processed

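The series measured RNA levels of mouse T helper 17 (Th17) cells by RNA sequencing of total RNA. Per the labels' protocols, CD4+ CD25- T cells of C57BL/6 spleen and lymph nodes were differentiated to day 4 with Arg C, linezolid or DMSO, and sorted by dilution of a division dye into cells of cycle 2 (1 division), cycle 3 (2 divisions) or cycle 4 (3 or more). Each of the 18 combinations of 2 experiments, 3 drugs and 3 cycles was sequenced as 3 libraries, 54 in all. The labels call these 3 technical replicates. By the sample identifiers they carry the same tag on 3 lanes, so they may be the same library sequenced again. Experiment 1 was on lanes 3 to 5 and experiment 2 on lanes 6 to 8, so lane is confounded with experiment. The labels state 100 µM linezolid and 60 mM Arg C. The unit of the second dose is printed here as labelled and could not be checked. CASAVA and the genome build GRCm38.p5 are named per the submitters' processing notes. The aligner, the counting tool, the annotation, the library kit and its strand are not given in the sources used here.

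The authors deposited 1 table of 45802 genes in 54 columns without a stated unit. Of the values of single-exon genes, 92.5% were whole multiples of 1 step per library, so the deposited values were read as RPKM, reads per kilobase of gene model and per 1e6 reads of the library. On this basis whole reads were recovered for all 19284 genes with any value, with a tolerance of 0.0001 of a read, and 61 of 66 single-exon genes checked had the length of their annotation. The libraries held between 8.0 and 12.5 M reads, and the 3 libraries of a sample together between 24.3 and 36.9 M. The spread between technical replicates was 1.04 to 1.12 times that of counting alone (chi-square over its degrees of freedom), so these 3 libraries were averaged and counted as 1 sample. Each drug and cycle then had n = 2 experiments, and each drug n = 6 samples. The 3 cycles of a drug and experiment are sorted fractions of treated cells and the fit takes them as independent, so a drug has 2 independent units, and errors and p-values of the comparisons over all cycles can be too small. The labels do not describe the animals of each experiment, and any difference between these is confounded with experiment.

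The plan set the test by the unit of the deposited file, so the test planned for normalised values was used. The recovered reads are derived from it and entered only alternatives and further tests. limma (version 3.58.1, R 4.3.3; lmFit and eBayes with trend) was fitted to log2(RPKM + 1) of all 18 samples, with 1 coefficient per drug and cycle and the experiment as a block, which left 8 residual degrees of freedom. Genes with at least 0.5 RPKM in at least 2 of the 18 samples were tested, 11004 in all. This filter was chosen after the unit was known, as the plan named a filter for counts only. A call is a Benjamini-Hochberg adjusted p under 0.05 over the 11004 genes with no fold minimum. Each fold change below is given with its standard error from this fit. A fold on this scale is understated for genes of a few RPKM or less. There were 17 contrasts, 39 gene lists fixed before the data were examined, and 36 lists with a tested gene. Lists were tested with limma's camera (preset correlation 0.01, and estimated as the alternative), adjusted over the lists of a contrast. None of the 36 lists was called in any of the 6 main contrasts with the estimated correlation.

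Named genes followed a rule set before the data were examined. For each of 3 main comparisons it took the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 RPKM and the same sign in every pair of samples, leaving out clone-like symbols. It added up to 4 genes per fixed list with the smallest p, and always a set that includes Il17a, Il17f, Ifng, Foxp3, Il10, Il2ra, Mki67, Atf4, Ddit3, Gfm1 and the protein genes of the mitochondrial genome, which are listed at 0. For Arg C against linezolid it took 5 rises and 5 falls. Not every gene that the rule takes is printed.

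The fit was tested on simulated reads drawn from the means of the DMSO samples, the residual spread and the depths, with 200 of 11004 genes changed. Rises and falls were equal in number, and the 18 samples were drawn as independent. Recovery and false calls where most genes change, with 2 independent units per drug, were thus not measured. For Arg C against DMSO over all cycles it recovered 48% of genes at the smallest fold simulated, 86% at 1.5-fold, 98% at 2-fold and 100% at 3-fold, and called 5 unchanged genes. For DMSO cycle 4 against cycle 2 it recovered 2%, 28%, 72% and 90%, and called 10 unchanged genes.

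The alternatives were upper-quartile rescaling, limma without trend, limma-voom on the recovered reads, no filter, a filter of 1 RPKM in 9 samples, no experiment block, the 54 libraries as own replicates or with a replicate block, each technical replicate, sample or experiment left out, only the groups of a contrast, mitochondrial and ribosomal-protein genes left out, a test against a fold of 1.5, and pseudocounts of 0.1 and 5. After the data were seen, 3 more were added: the 3 cycles of each drug and experiment averaged (2 units per drug, 2 residual degrees of freedom), median-ratio scaling from the recovered reads, and removal of each sample's trend over gene-model length and GC content (polynomials of degree 3). Genes listed at 0 in every library were left out. These included the 12 protein genes of the mitochondrial genome that the table lists and Trac, Trbc1 and Trbc2, so the table cannot show their level. Intervals on list gaps come from 2000 bootstrap draws over genes. Further tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.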

Results

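The data are RNA levels of mouse Th17 cells, helper T cells that make interleukin 17, cultured for 96 h with Arg C, linezolid or the vehicle DMSO. Argyrin C (Arg C) and the antibiotic linezolid are both known to inhibit protein synthesis in mitochondria. The compounds are structurally unrelated and their labelled doses differ, 60 mM for Arg C (unit as labelled) and 100 µM for linezolid. Cells were sorted by the number of divisions, so that drug and vehicle were compared at the same cycle. There were 18 samples, 6 per drug, from 2 experiments and 3 cycles (sorted fractions, so 2 independent units per drug), with 24.3 to 36.9 M reads each. The first principal component held 70.8% of the variance and parted DMSO from Arg C samples.

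Ribosomal-protein genes took 15.3 to 16.7% of the reads in genes in DMSO libraries, 18.7 to 24.4% with linezolid and 24.8 to 28.3% with Arg C. A larger share for these genes lowers the RPKM of others, and how much of the shift below this explains was not measured. With mitochondrial and ribosomal-protein genes left out, the counts called with each drug over all cycles stayed within a factor of 1.5. Of 146 named-gene values 142 then kept sign and call, and 0 reversed. The total count cannot show how far the shift depends on scaling. With median-ratio scaling the Arg C total was 9121 against 9519, while genes called higher went from 1820 to 4415. The median log2 change of all 11004 tested genes was -0.47 with Arg C and -0.21 with linezolid, and -0.02 and 0.01 with median-ratio scaling, an alternative chosen after the data were seen. Values below are on the deposited RPKM scale, and values in parentheses after a gene are log2 fold changes with standard errors. The change of a gene relative to the other genes is its value set against these medians, and a direction that depends on the scaling is said to do so.

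The first comparison asked what Arg C changes in Th17 cells at matched division cycle, where cycle 4 holds cells of 3 or more divisions. Genes of glycolysis and targets of the hypoxia factor HIF-1 were among those that fell furthest. Bnip3, a mitophagy receptor gene, went from 137 ± 12.6 RPKM (SD, n = 6) in DMSO to 1.59 ± 0.505 in Arg C, a log2 fold change of -5.75 ± 0.11. Il17a, which encodes the cytokine that names these cells, went from 36.2 ± 17.2 to 3.35 ± 1.35 RPKM, and Mki67, a proliferation marker, from 10.7 ± 4.19 to 35.1 ± 12.6. All 3 differences passed limma's test, and each had the same sign in 6 of 6 pairs of samples.

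All 21 tested glycolysis genes fell with Arg C, also when adjusted over the list alone. Among them Tpi1, which encodes triose phosphate isomerase, fell (-3.76 ± 0.05), the enolase gene Eno1 (-3.40 ± 0.06), the pyruvate kinase gene Pkm (-2.62 ± 0.05), the phosphofructokinase gene Pfkl (-4.48 ± 0.11) and the lactate exporter gene Slc16a3 (-4.23 ± 0.10). The list's camera test (limma) gave adjusted p = 4.31e-06, and adjusted p = 0.267 with an estimated correlation. All 18 tested genes of the HIF-1 list fell as well, and all 18 adjusted over the list alone. The list's camera test gave adjusted p = 3e-05 in limma and adjusted p = 0.282 with an estimated correlation. Besides targets, the list holds Hif1a, the gene of the factor itself, at -1.44. The prolyl hydroxylase genes Egln3 and P4ha2 fell (-5.02 ± 0.08 and -4.33 ± 0.08), and Ero1l, an oxidase of the endoplasmic reticulum, (-3.50 ± 0.07).

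Of 18 tested Th17 genes, 17 fell and 1 rose with Arg C, the same numbers adjusted over the list alone (camera adjusted p = 0.00597 in limma; adjusted p = 0.339 with an estimated correlation). Il17a fell (-3.02 ± 0.11), Il17f (-3.23 ± 0.10), and the cytokine genes Il21 and Tgfb3 (-2.88 ± 0.07 and -4.10 ± 0.07). The transcription factor genes Irf4 and Batf fell (-4.60 ± 0.18 and -1.53 ± 0.05), and Il10 (-2.09 ± 0.08). Tnfrsf9 and Il2ra, receptor genes of activated T cells, fell (-5.12 ± 0.17 and -1.67 ± 0.12). Foxp3, the factor of regulatory T cells, was 0.28 ± 0.10 RPKM in DMSO and 0.63 ± 0.13 in Arg C and rose (0.35 ± 0.07). Of 10 tested regulatory T cell genes 1 rose and 8 fell, the same adjusted over the list alone (camera adjusted p = 0.312 in limma; adjusted p = 0.845 with an estimated correlation). Ifng, below the filter, was at 0.04 ± 0.05 RPKM in DMSO and was not tested.

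Cell cycle genes rose with Arg C. Of 22 G2/M genes 21 rose, none fell and 1 was not called (camera adjusted p = 1.06e-16 in limma; adjusted p = 0.267 with an estimated correlation), and of 22 S phase genes 16 rose, 3 fell and 3 were not called (camera adjusted p = 1.93e-10; adjusted p = 0.267 with an estimated correlation). Both counts were the same adjusted over the list alone. The mitotic genes Top2a, Ccnb2 and Kif20a rose (1.88 ± 0.12, 1.76 ± 0.12 and 1.81 ± 0.14), the replication genes Cdc45 and Mcm5 (1.58 ± 0.08 and 1.51 ± 0.09), and Cdca5, a cohesin regulator, (2.38 ± 0.12). The 3 S phase genes that fell on the RPKM scale were not lower with median-ratio scaling, where 19 rose and 0 fell.

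Genes of the mitochondrion moved in both directions. All 11 tested nuclear genes of respiratory complex IV rose, adjusted over the list alone too, with Cox8a at 0.74 ± 0.05 and Cox5a at 0.55 ± 0.04 (camera adjusted p = 1.9e-08 in limma; adjusted p = 0.267 with an estimated correlation). Across all genes, the fold change with Arg C followed model length and mean RPKM (Spearman's rho -0.196 and 0.159, not independent replicates). Its median was 0.049 for genes of up to 1000 bp and -0.572 for those above 4000 bp. The mitochondrial lists were not matched on length or level, so such trends are not separated from their changes. Of 77 mitochondrial ribosomal-protein genes 21 rose and 39 fell, the same adjusted over the list alone, and with median-ratio scaling 54 rose and 8 fell, so their direction depends on the scaling (camera adjusted p = 0.0179 in limma, upward; adjusted p = 0.587 with an estimated correlation). The citrate synthase gene Cs rose (0.83 ± 0.05). The mitochondrial chaperonin genes Hspe1 and Hspd1 rose (1.40 ± 0.05 and 0.80 ± 0.04), while the protease genes Afg3l2 and Lonp1 fell (-2.68 ± 0.06 and -1.54 ± 0.07). Gfm1, which encodes the mitochondrial elongation factor that argyrin C is known to bind, was at -0.21 ± 0.05 on the RPKM scale and 0.37 with median-ratio scaling, so its direction depends on the scaling. Rnr2, the large ribosomal RNA of the mitochondrial genome, fell (-1.14 ± 0.20), and Rnr1, the small one, was at -0.41 ± 0.13 on the RPKM scale and 0.22 with median-ratio scaling, lower in 4 of 6 pairs.

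The list for ATF4, the transcription factor of the integrated stress response, holds Atf4 itself besides targets. Of its 27 tested genes 12 rose and 11 fell, the same adjusted over the list alone, and 18 rose and 8 fell with median-ratio scaling (camera adjusted p = 0.000203 in limma, upward; adjusted p = 0.267 with an estimated correlation). Mthfd2, of mitochondrial folate metabolism, rose (1.42 ± 0.04) and the asparagine synthetase gene Asns (1.62 ± 0.05), whereas the lipoprotein receptor gene Vldlr fell (-2.45 ± 0.07) and the hormone gene Stc2 (-1.77 ± 0.07). Ddit3, a stress factor, rose (0.64 ± 0.06). Atf4 itself was at 0.09 ± 0.06 (limma, adjusted p = 0.184), higher in 3 of 6 pairs. Among tRNA synthetase genes, Aars rose (1.13 ± 0.05) and Dars fell (-1.47 ± 0.07).

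Ribosomal-protein genes rose, 76 of 79, while 2 fell and 1 was not called, the same adjusted over the list alone (camera adjusted p = 2.96e-42 in limma; adjusted p = 0.267 with an estimated correlation). Rpl22l1 rose (1.35 ± 0.06). The gap of the list was 0.36 against genes of like mean RPKM and model length, and 1.19 against all genes. H2-Ab1, a class II antigen gene that serves as a marker of dendritic cells, fell (-3.01 ± 0.09), and the interferon target Gbp2 (-2.83 ± 0.14).

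The largest rises with Arg C were in the heat shock genes Hspa1b and Hspa1a, near-identical copies whose reads may be shared. Hspa1b went from 0.73 ± 0.16 RPKM (SD, n = 6) to between 46.4 and 211 RPKM and rose (5.94 ± 0.25), and Hspa1a (5.80 ± 0.29). Rnu3b3, one of several U3 small nucleolar RNA copies, rose (3.50 ± 0.20), and Rn7sk (2.27 ± 0.20).

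In limma 9519 of 11004 genes were called with Arg C, 1820 higher and 7699 lower, and 185 and 2270 of these changed at least 2-fold. With median-ratio scaling 4415 were higher and 4706 lower. Experiment 1 alone gave 1422 higher and 7456 lower, and experiment 2 alone 1663 and 7083. Within an experiment the 3 cycles of a drug are fractions of the same treated cells, so these counts hold no variation between cultures. With the 3 cycles averaged, 2 units per drug, limma called 1354 higher and 6859 lower.

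**Figure D1:**
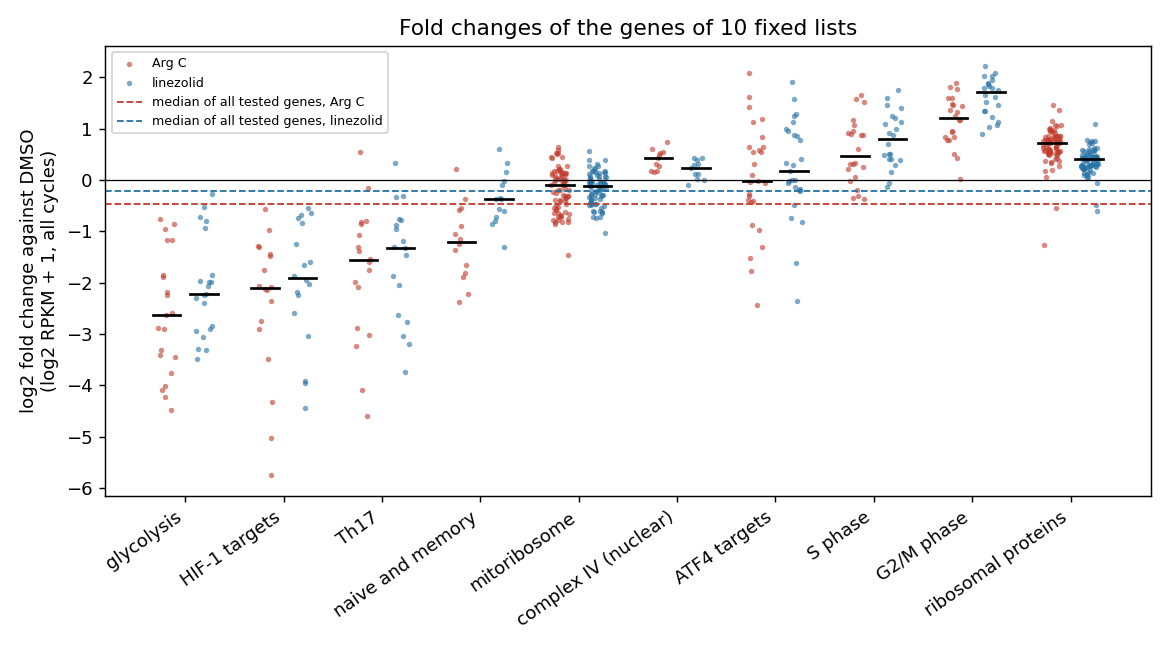
Log2 fold change against DMSO (y axis, log2 RPKM + 1, mean of 3 cycles) of each tested gene of 10 fixed lists (x axis) with Arg C and with linezolid. Points are genes, black bars list medians and dashed lines the medians of all tested genes, -0.47 and -0.21; all glycolysis and HIF-1 genes lie below 0 with both drugs.

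**Figure D2:**
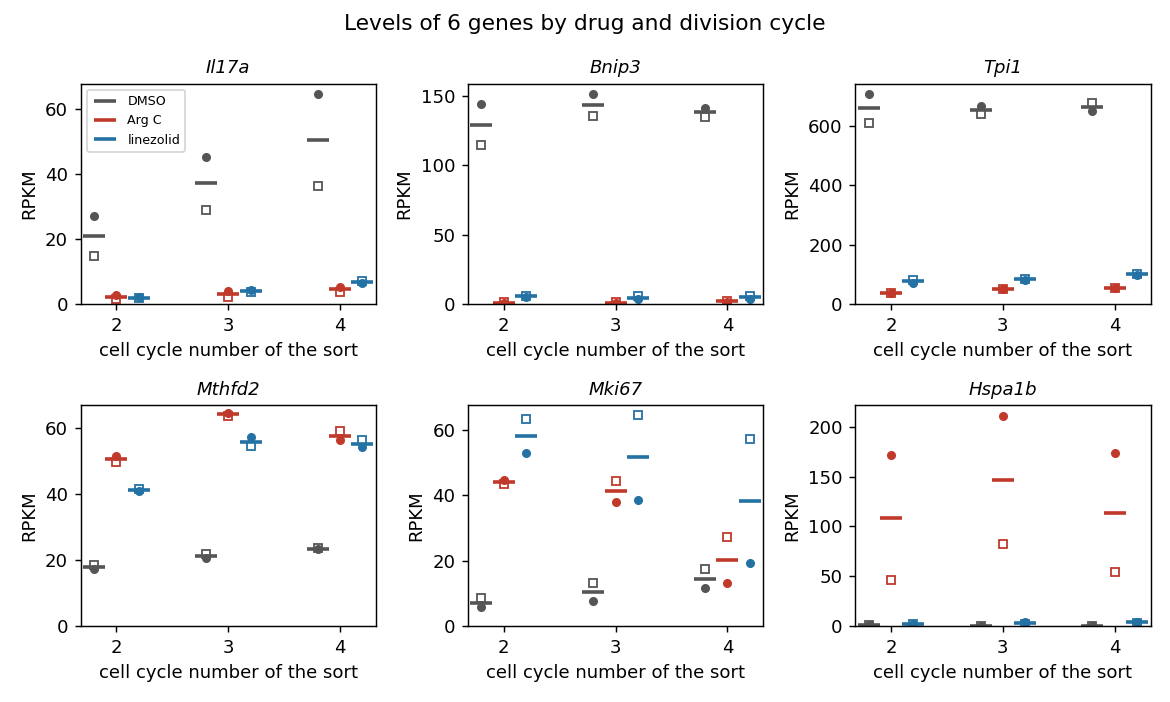
RPKM (y axis) of 6 genes by division cycle (x axis) and drug, where circles are experiment 1, squares experiment 2 and horizontal marks their mean. Il17a, Bnip3 and Tpi1 are lower in all samples with either drug at the same cycle, and Hspa1b is high in the Arg C samples.

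Linezolid was compared with DMSO in the same way. Bnip3 fell (-4.44 ± 0.11) to 5.41 ± 1.15 RPKM, Il17a (-2.78 ± 0.11) to 4.33 ± 2.21 RPKM, and Mki67 rose (2.08 ± 0.16) to 49.3 ± 17.4 RPKM (SD, n = 6). Genes of the glycolysis and HIF-1 lists fell, 21 of 21 and 18 of 18, the same adjusted over the lists alone. Camera gave adjusted p = 1.14e-08 and 1.55e-07 in limma, and adjusted p = 0.29 with an estimated correlation in both. Hif1a was at -0.64. With median-ratio scaling 20 of the 21 glycolysis genes fell. Tpi1 fell (-2.90 ± 0.05), Eno1 (-2.85 ± 0.06), Pkm (-2.31 ± 0.05) and the glucose transporter gene Slc2a1 (-2.95 ± 0.06). Egln3, P4ha2 and Ero1l fell (-3.92 ± 0.08, -3.95 ± 0.08 and -3.04 ± 0.07).

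Of 18 Th17 genes 17 fell and 1 rose with linezolid, the same adjusted over the list alone (camera adjusted p = 7.16e-05 in limma; adjusted p = 0.29 with an estimated correlation). Il17f fell (-3.04 ± 0.10), Il21 (-2.63 ± 0.07), Tgfb3 (-3.75 ± 0.07) and Il10 (-2.05 ± 0.08). Tnfrsf9, Il2ra and the growth regulator gene Myc fell (-4.11 ± 0.17, -1.44 ± 0.12 and -1.98 ± 0.13), and Foxp3 rose (0.42 ± 0.07), while of 10 regulatory T cell genes 2 rose and 7 fell, the same adjusted over the list alone (camera adjusted p = 0.235 in limma; adjusted p = 0.761 with an estimated correlation). All 22 G2/M genes and 20 of 22 S phase genes rose, with 0 and 1 lower, the same adjusted over the lists alone (camera adjusted p = 1.81e-16 and 1.05e-11 in limma; adjusted p = 0.29 with an estimated correlation in both). Top2a, Ccnb2, Kif20a, Kif2c and the mitotic factor gene Foxm1 rose (2.02 ± 0.12, 1.95 ± 0.12, 2.21 ± 0.14, 2.29 ± 0.13 and 2.12 ± 0.15), and Cdc45 and Mcm5 (1.76 ± 0.08 and 1.60 ± 0.09).

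Of the 27 genes of the ATF4 list 14 rose and 7 fell with linezolid, 14 and 8 adjusted over the list alone, and 17 and 4 with median-ratio scaling (camera adjusted p = 0.0006 in limma; adjusted p = 0.29 with an estimated correlation). Mthfd2 rose (1.24 ± 0.04), Asns (1.58 ± 0.05), the serine synthesis gene Phgdh (1.29 ± 0.05), Ddit3 (0.87 ± 0.06) and Aars 2.38-fold, while Vldlr and Dars fell (-2.35 ± 0.07 and -1.32 ± 0.07). Atf4 was at -0.14 ± 0.06 (limma, adjusted p = 0.0515) and Gfm1 at -0.19 ± 0.05, and with median-ratio scaling at 0.15 and 0.07, so the direction of both depends on the scaling. Hspe1 rose (1.03 ± 0.05) and Cs (0.67 ± 0.05), and Afg3l2 and Lonp1 fell (-2.05 ± 0.06 and -1.46 ± 0.07). Of 11 complex IV genes 7 rose and 1 fell, 8 and 1 adjusted over the list alone, and 11 and 0 with median-ratio scaling (camera adjusted p = 0.00185 in limma; adjusted p = 0.588 with an estimated correlation). Cox5a and Cox8a rose (0.42 ± 0.04 and 0.40 ± 0.05). The complex IV list was again not matched on length or level. Of 77 mitochondrial ribosomal-protein genes 12 rose and 38 fell, the same adjusted over the list alone, and 38 and 17 with median-ratio scaling (camera adjusted p = 0.963 in limma; adjusted p = 0.988 with an estimated correlation). Rnr2 fell (-1.68 ± 0.20), H2-Ab1 (-2.76 ± 0.09) and Gbp2 (-2.92 ± 0.14). Ribosomal-protein genes rose, 69 of 79, with 2 lower, and 70 and 2 adjusted over the list alone (camera adjusted p = 2.76e-20 in limma; adjusted p = 0.5 with an estimated correlation), with Rpl22l1 at 0.76 ± 0.06. Hspa1b and Hspa1a rose with linezolid too (1.23 ± 0.25 and 1.30 ± 0.29), Hspa1b to 3.17 ± 1.13 RPKM. The list's gap to genes of like mean RPKM and length was 0.26, of 0.61 against all genes.

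In limma 8303 genes were called with linezolid, 2307 higher and 5996 lower, of which 218 and 733 changed at least 2-fold. With median-ratio scaling 4135 were higher and 4017 lower. Experiment 1 alone gave 1747 higher and 6053 lower, and experiment 2 alone 2316 and 4586, again without variation between cultures. With the 3 cycles averaged limma called 1500 higher and 4496 lower.

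The changes with each drug were alike across genes: 1515 genes were higher and 5828 lower with both, and 261 were called in opposite directions. If calls fell independently, 382 and 4195 would be shared. With median-ratio scaling 3448 were higher and 3552 lower with both, against 1659 and 1718, so the excess of shared falls over shared rises depends on the scaling. Pearson's r between the fold changes was 0.892 and Spearman's rho 0.875, across genes, which are not independent replicates. Both drugs were set against the same DMSO samples, and simulated unchanged groups with shared controls gave a mean r of 0.498 and no shared call. With separate DMSO samples, Arg C of experiment 1 against linezolid of experiment 2 gave r = 0.736, 962 genes higher and 4281 lower with both, and 609 in opposite directions. The reverse gave r = 0.924 with 1297, 5738 and 49. These calls come from fits of single experiments, which hold no variation between cultures.

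**Figure D3:**
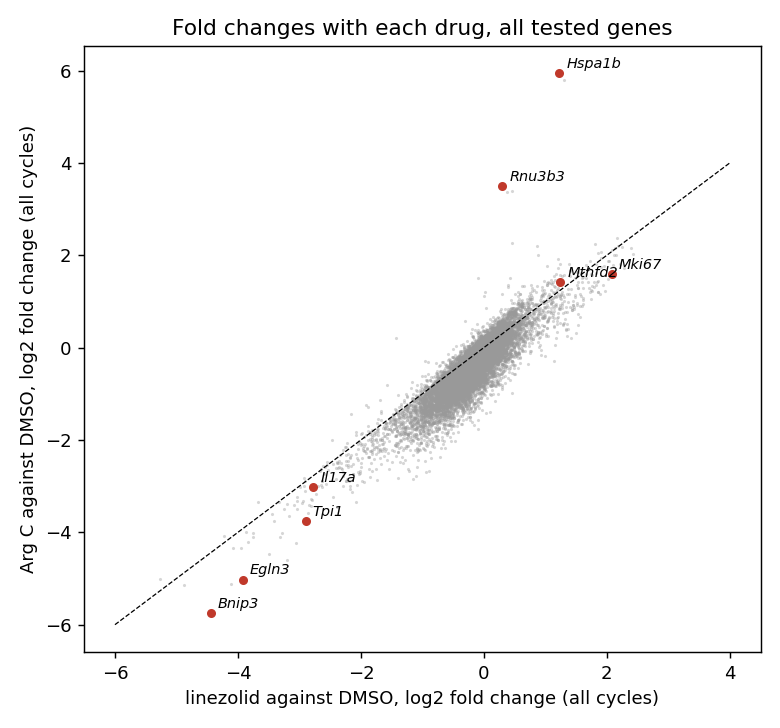
Log2 fold change with Arg C (y axis) against that with linezolid (x axis), log2 RPKM + 1 and mean of 3 cycles, for the 11004 tested genes. Points are genes, the dashed line marks equal change, and Hspa1b and Rnu3b3 lie above it.

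Arg C and linezolid were compared directly to test where the drugs differ. Hspa1b and Hspa1a were higher with Arg C (4.71 ± 0.25 and 4.50 ± 0.29), and the U3 copies Rnu3b3, Rnu3b1 and Rnu3b2 (3.20 ± 0.20, 2.98 ± 0.23 and 2.93 ± 0.24). Slc9a3r1, Slfn2, Gpr146, Klf13 and Il6st, the gene of a shared interleukin 6 receptor chain, were lower with Arg C at -1.77 ± 0.18, -1.74 ± 0.25, -1.69 ± 0.14, -1.69 ± 0.15 and -1.67 ± 0.18. All 14 tested genes of naive and memory T cells were lower with Arg C than with linezolid, all 14 adjusted over the list alone, and 13 with median-ratio scaling (camera adjusted p = 0.00174 in limma; adjusted p = 0.633 with an estimated correlation). Of 79 ribosomal-protein genes 74 were higher with Arg C and 1 lower, the same adjusted over the list alone (camera adjusted p = 3.35e-49 in limma; adjusted p = 0.206 with an estimated correlation). In limma 841 genes were higher and 6576 lower with Arg C, 12 and 227 of them at least 2-fold, around a median of all genes of -0.23, and with median-ratio scaling 3137 and 3500. Arg C against linezolid over all cycles gave 401 and 4301 without experiment 2, and 695 and 6132 without experiment 1, in fits without variation between cultures. With the 3 cycles averaged limma called 188 higher and 3862 lower. The fold change followed model length across genes (Spearman's rho -0.378, not independent replicates): its median was 0.08 for genes of up to 1000 bp and -0.34 for those above 4000 bp.

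In vehicle cells, cycle 4 was compared with cycle 2 to show how cells with more divisions differ. Il17a rose (1.23 ± 0.20), from 20.9 ± 8.55 RPKM at cycle 2 to 50.5 ± 19.9 at cycle 4 (SD, n = 2), and Il17f (1.06 ± 0.17). Psat1, Asns and Phgdh, of serine and asparagine synthesis, rose (0.91 ± 0.09, 0.88 ± 0.09 and 0.73 ± 0.09), and Stc2 (0.73 ± 0.11). Single cytotoxic and Th1 genes fell: the granzyme gene Gzma (-1.62 ± 0.30), the perforin gene Prf1 (-0.71 ± 0.12), the chemokine gene Ccl5 (-1.46 ± 0.19), Nkg7 (-1.25 ± 0.27), Cxcr3 (-0.73 ± 0.18) and the Th1 factor gene Tbx21 (-0.49 ± 0.13).

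Of the 27 genes of the ATF4 list 10 rose and 0 fell at cycle 4, and 14 rose adjusted over the list alone (camera adjusted p = 1.24e-05 in limma; adjusted p = 0.161 with an estimated correlation). Of 20 tRNA synthetase genes 4 rose, and 10 adjusted over the list alone (camera adjusted p = 7.99e-06; adjusted p = 0.136 with an estimated correlation), with Tars at 0.46 ± 0.06 and Eprs at 0.43 ± 0.08. Of 8 Th1 genes 4 fell, and 6 adjusted over the list alone (camera adjusted p = 7.99e-06; adjusted p = 0.161 with an estimated correlation). Of 6 cytotoxic genes 2 fell and 4 were not called, and 4 fell adjusted over the list alone (camera adjusted p = 0.000919; adjusted p = 0.25 with an estimated correlation). Markers of other cells moved as well: the CD8 gene Cd8b1 and 1 of 2 myeloid markers were lower, and 1 of 2 NK markers and 1 of 3 B cell markers were higher. Of 16 activation genes 5 fell, and 7 adjusted over the list alone (camera adjusted p = 5.05e-05; adjusted p = 0.136 with an estimated correlation), with Lag3, Nr4a1 and Tigit at -0.91 ± 0.12, -0.84 ± 0.13 and -0.83 ± 0.14. The Th2 factor gene Gata3 fell (-1.35 ± 0.20), Cd7 (-1.73 ± 0.15), Ms4a4b (-1.84 ± 0.40), Tgfb3 (-0.63 ± 0.12), Usp18 (-0.99 ± 0.14), and Tcf7 and Klf2, of naive T cells, (-0.63 ± 0.09 and -0.75 ± 0.14). Procr, Pdpn, Fabp5, Csf2, Hspe1 and Hspd1 rose (1.70 ± 0.16, 1.68 ± 0.13, 1.08 ± 0.09, 0.35 ± 0.08, 0.67 ± 0.08 and 0.46 ± 0.07). The mean of Csf2 over all DMSO samples was only 0.43 RPKM. Of 22 G2/M genes 2 rose and 0 fell, 13 rose adjusted over the list alone, and 0 were called with median-ratio scaling (camera adjusted p = 1.43e-06; adjusted p = 0.391 with an estimated correlation). Mki67 was at 0.91 ± 0.27 (limma, adjusted p = 0.0616). Foxp3, Il10, Il2ra, Atf4, Ddit3 and Gfm1 were not called, at 0.20 ± 0.13, 0.27 ± 0.14, 0.52 ± 0.21, 0.04 ± 0.11, -0.06 ± 0.10 and 0.18 ± 0.09.

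In limma 490 genes were higher and 354 lower at cycle 4 than at cycle 2. With only these groups in the fit 2200 were called, by limma-voom 548, and without the experiment block 293. Between cycles 3 and 2 there were 5 and 6, and in all 754 with only these groups, 49 with no filter and 0 by limma-voom. Between cycles 4 and 3 limma called 0, with 308 higher and 266 lower at an unadjusted p under 0.05 and 0 calls by limma-voom, but 776 with only these groups and 28 with no filter. Each arm has 2 samples, and the count fell from 844 to 253 without the cycle 2 sample of experiment 1, to 292 without that of experiment 2, to 413 without the cycle 4 sample of experiment 1 and was 569 without that of experiment 2. The fold change followed GC content across genes (Spearman's rho -0.299).

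The effect of each drug was also compared between cycles 4 and 2. The rise of mitotic genes was smaller at cycle 4: all 22 G2/M genes with Arg C and 20 of 22 with linezolid had a smaller effect there, 22 of 22 with each adjusted over the list alone (camera adjusted p = 1.72e-23 and 1.05e-16 in limma; adjusted p = 0.54 and adjusted p = 0.591 with an estimated correlation). With Arg C, Mki67 was higher than in DMSO by 2.47 ± 0.27 at cycle 2 and 0.39 ± 0.27 at cycle 4 (limma, adjusted p = 0.207 at cycle 4), a difference of -2.08 ± 0.38. With linezolid the values were 2.86 ± 0.27 and 1.17 ± 0.27, a difference of -1.69 ± 0.38. In DMSO Mki67 stood at 7.23 ± 1.87 RPKM at cycle 2 and 14.5 ± 4.01 at cycle 4 (SD, n = 2). The difference between cycles was called in limma for 871 genes with Arg C, 468 higher and 403 lower (315 and 617 with median-ratio scaling), and for 593 with linezolid, 226 and 367 (156 and 491). Without the experiment block these counts were 100 and 0, and with only the groups of the contrast 241 and 0. Leaving out 1 sample moved the count for Arg C to between 286 (without the cycle 4 Arg C sample of experiment 1) and 893. For linezolid it moved to between 97 and 1233, without the cycle 4 DMSO sample of experiment 1 and of experiment 2.

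Coordinates of a few of these genes in GENCODE M21, for the GRCm38 assembly, are: Il17a on chromosome 1 from 20730905 to 20734496, Bnip3 on chromosome 7 from 138890836 to 138909519, Tpi1 on chromosome 6 from 124810586 to 124814296, Mki67 on chromosome 7 from 135689784 to 135716361, and Hspa1b on chromosome 17 from 34956436 to 34959238.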

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

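The tests of drug by experiment were chosen only after the result was seen, and the tests between cycles were planned. The results stand here because the effect of a drug differed between cycles or experiments.

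The effect of a drug differed between cycle 4 and cycle 2 for 871 genes with Arg C and 593 with linezolid (limma, n = 2 experiments). Without the experiment block these counts were 100 and 0, and with only the groups of the contrast 241 and 0. The proliferation marker Mki67 had a smaller rise at cycle 4 with Arg C (difference -2.081 ± 0.38) and linezolid (-1.688 ± 0.38). For the mitotic genes Top2a and Ccnb2 with Arg C the differences were -1.432 ± 0.29 and -2.091 ± 0.28, and for Ccnb2 with linezolid -1.749 ± 0.28. Top2a with linezolid was not called, at -1.04 ± 0.29 (limma, adjusted p = 0.0608). In DMSO the level of Mki67 at cycle 4 was 14.5 ± 4.01 RPKM against 7.23 ± 1.87 at cycle 2, and with Arg C it was 20.2 ± 10.1 against 44.0 ± 0.816 (SD, n = 2). The cause was not tested.

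The effect of a drug was also called different between the experiments for 3925 genes with Arg C (3327 higher and 598 lower in experiment 2) and 4880 with linezolid (4132 and 748), in a limma fit with 6 residual degrees of freedom, and for 3226 and 4072 with median-ratio scaling. The residual comes from sorted fractions of the same treated cells, so variation between cultures is not separated from the experiments. Effects were smaller in experiment 2 for 78.8% of the genes called with Arg C and 75.7% of those called with linezolid. These directions and percentages are given on the RPKM scale only. The share of reads in ribosomal-protein genes also differed: with Arg C it was 27.37 to 28.33% in experiment 1 and 24.77 to 25.44% in experiment 2. With linezolid it was 21.81 to 24.41% and 18.65 to 19.6%. Across genes, which are not independent replicates, the slope of experiment 2 on experiment 1 was 0.804 and 0.757, with r = 0.947 and r = 0.901. The cause was not tested, and each drug, cycle and experiment has 1 sample. Any difference between the animals or the handling of the experiments is confounded with experiment.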

How the results depend on the processing

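Alternatives are those in the processing notes, and the ones added after the data were seen were median-ratio scaling, removal of length and GC trends, and the cycles averaged per drug and experiment. Of 4508 named-gene values under these settings 4326 kept sign and call, 135 lost the call, 32 gained one and 15 reversed. The 15 are of Atf4, Gfm1, Ddit3, Rnr1 and Cd8b1. With upper-quartile rescaling Gfm1 was at 0.44 with Arg C and 0.07 with linezolid, Rnr1 and Cd8b1 at 0.30 and 0.21 with Arg C, and Atf4 at 0.14 with linezolid. With median-ratio scaling Gfm1 was at 0.37 and 0.07, Rnr1 and Cd8b1 at 0.22 and 0.14 with Arg C, and Atf4 at 0.15 with linezolid. Without experiment 1 Atf4 was at -0.05 with Arg C, and without experiment 2 at 0.03 with linezolid. In DMSO cycle 4 against cycle 2, Atf4 was at -0.01 without the cycle 2 sample of experiment 1 and -0.13 without the cycle 4 sample of experiment 2 (highest 0.21), and Ddit3 at 0.13 without the cycle 4 sample of experiment 1 (lowest -0.24). With the 54 libraries as own replicates the counts for Arg C against linezolid at cycles 3 and 4 went from 3994 and 4032 to 7180 and 7359, those for DMSO cycles 4 against 2, 3 against 2 and 4 against 3 from 844, 11 and 0 to 4632, 1805 and 1213, and those for the difference of the drug effects between cycles from 871 and 593 to 4659 and 4980. With the replicate block they were, in the same order, 7109, 7287, 4479, 1649, 1099, 4527 and 4806; counting technical replicates as samples lowers the error. Without the experiment block 6 of these were 1782, 1983, 293, 4, 100 and 0, leaving out cycles 4 against 3. With only the groups of a contrast, linezolid at cycle 4 gave 3384 (6417 before), the DMSO cycles 2200, 754 and 776, and the drug effects 241 and 0. Against a fold of 1.5 the counts were 3868 for Arg C, 1549 for linezolid and 265 between the drugs over all cycles, 2938, 1005 and 5 at cycle 2, 3050, 1124 and 7 at cycle 3, 2720, 807 and 5 at cycle 4, 6 and 0 for DMSO cycles 4 and 3 against 2, and 0 and 0 for the drug effects between cycles. limma-voom gave 548 and 0 for DMSO cycles 4 and 3 against 2 and 377 for the linezolid effect between cycles. DMSO cycle 3 against 2 gave 6 with upper-quartile rescaling, 7 without trend, 49 with no filter, 1 with pseudocount 0.1 and 41 with pseudocount 5, and cycle 4 against 3 gave 28 with no filter. Arg C against linezolid gave 4702 without experiment 2, a fit without variation between cultures, and 4050 with the cycles averaged (7417 before). Leaving out 1 sample or replicate gave 9289 to 9532 for Arg C, 7791 to 8361 for linezolid and 6692 to 7549 between the drugs, and by cycle between the drugs 3025 to 5485, 1005 to 3791 and 1266 to 4636 (lowest without the Arg C sample of experiment 1 each time). For DMSO cycles 4 and 3 against 2 it gave 253 to 716 and 0 to 14, and for the drug effects between cycles 286 to 893 and 97 to 1233. With an estimated correlation the lists called went from 15, 12, 11, 20, 9 and 11 to 0 in each of the 6 contrasts. The correlation of the drugs' fold changes across genes, which are not independent replicates, went from 0.892 to 0.736 and 0.924 across experiments, 0.895 with median-ratio scaling and 0.498 in simulated unchanged groups, where 0 genes were called with both.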

Other observations

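Further lists of nuclear genes for mitochondria were tested with Arg C, also without matching on length or level. Of 36 complex I genes 12 rose and 12 fell, the same adjusted over the list alone, and 32 rose and 0 fell with median-ratio scaling, so their direction depends on the scaling (camera adjusted p = 3e-05 in limma, upward; adjusted p = 0.267 with an estimated correlation). Of 20 mitochondrial translation and transcription factors 2 rose and 16 fell, the same adjusted over the list alone, and 8 and 10 with median-ratio scaling (camera adjusted p = 0.576 in limma; adjusted p = 0.845 with an estimated correlation). Of 18 genes of the citric acid cycle 8 rose and 8 fell, the same adjusted over the list alone, and 14 and 2 with median-ratio scaling (camera adjusted p = 0.0125 in limma, upward; adjusted p = 0.282 with an estimated correlation). Among markers of other cell types, the class II genes H2-Ab1 and Cd74 moved apart: H2-Ab1 had a mean of 86.4 RPKM in DMSO, 9.80 with Arg C and 11.9 with linezolid, Cd74 9.92, 15.3 and 12.1, and the further class II gene H2-Aa 0.69, 0.118 and 0.186. All 3 tested B cell markers fell with each drug, the same adjusted over the list alone (camera adjusted p = 0.648 with Arg C and 0.334 with linezolid in limma; adjusted p = 0.845 and adjusted p = 0.588 with an estimated correlation). Among these Cd79b went from a mean of 1.56 RPKM in DMSO to 0.42 and 0.889, and Ebf1 from 0.723 to 0.0107 and 0.0244. Fcmr, the remaining marker, was at -0.229 with Arg C and -0.452 with linezolid. With Arg C it fell less than the median of all tested genes (-0.474), so its direction there can depend on the scaling. Cd8b1 had means of 7.52, 5.48 and 6.32 RPKM, and with Arg C it was lower on the RPKM scale and higher with median-ratio scaling.

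In this part, the tests of reads freed by other transcripts, of GC content, length or mean RPKM alone, of short RNA from reads, of the other heat shock genes and of median-ratio scaling were chosen only after the result was seen. Other splits of the same 12 samples into 6 and 6 were also counted, 100 of them per comparison with the real one included, in fits of those samples alone. For each comparison 1 of 100 splits, the real one, gave as many genes. The samples are fractions of 2 units per drug, and 2 against 2 units make 3 splits, too few for a share under 0.05. For Arg C against DMSO the real split gave 9306 genes and the highest other 7126, for linezolid 7967 and 4580, and for Arg C against linezolid 7907 and 5204. The replicate numbers do not pair samples: residuals of libraries from the same lane had a mean correlation of 0.002.

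Ribosomal-protein genes were higher with both drugs, by a median of 1.19 with Arg C and 0.61 with linezolid against all genes. Matching was run in 5 forms: the gap was 0.355 (0.264 to 0.468) to genes of like level and length and 0.278 (0.188 to 0.366) to genes of like level and GC content, both set beforehand, and 1.18 for GC content alone, 0.78 for length alone and 0.516 for mean RPKM alone. GC content alone is argued against. The test of reads freed by other transcripts cannot decide: all genes had a median change of -0.474 with Arg C, and 7699 of 11004 were called lower. If most transcripts fell, the reads they freed could raise the rest while that median stayed negative. A bias by level together with GC content stays open as a possible explanation, and one by level and length cannot be told apart from a change in these genes, as the gap shrinks but does not close. Pseudogenes of ribosomal proteins are among the matched genes and may share their reads, which was not tested.

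Hspa1b, Hspa1a, the U3 copies and Rn7sk were higher with Arg C than with linezolid or DMSO. A greater share of short RNA in the Arg C libraries stays open for U3 and Rn7sk. It was tested with 15 other genes annotated as small nuclear, small nucleolar, guide or miscellaneous RNA. Their median gap was 0.447 (0.175 to 0.576), but 12 of them lie under 1 RPKM, where the planned test cannot tell. From their reads the gap was 1.331 (0.102 to 1.86), above 1 for 9 genes. The set may hold RNA that is not short: Gm8995, Slfn10-ps and 3110053B16Rik were at -0.97, -0.904 and -0.323 from reads. All its other genes had a positive gap from reads. Heat or handling stress cannot be told apart from an effect of Arg C: the other 9 cytosolic heat shock genes were at 0.183 (-0.106 to 0.64), with Hspb1 (1.20), Hsp90ab1 (0.41) and Hspa8 (0.28) higher and 3 lower, and of all 11 genes of the list 8 were higher and 0 lower with median-ratio scaling. Proteasome inhibition at 96 h is argued against by 37 proteasome genes, which as a set were not higher, at 0.038 (-0.02 to 0.129). Earlier or partial inhibition was not tested. What else differs between the compounds or their doses, and reads shared between Hspa1a and Hspa1b, were not tested.

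Glycolysis and HIF-1 target genes were lower with both drugs. Bias by abundance or length is argued against by a median gap of -2.189 (-2.755 to -1.512) to matched genes with Arg C and -1.97 with linezolid, and the share of reads taken by ribosomal-protein genes by a median of -1.741 and -1.727 with median-ratio scaling. Lower activity of HIF-1 stays open: 12 further target genes had a gap of -1.459 (-2.569 to -1.017) with Arg C and -1.265 with linezolid. Lower activity of Myc also stays open, with 20 nucleolar and growth genes at -0.639 (-0.859 to -0.006) and -0.689. That inhibition of mitochondrial protein synthesis lowers HIF-1 activity here is a hypothesis that these data do not test.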
